A study of Rattus norvegicus with 16 samples.

How the data were processed

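Liver messenger RNA was sequenced from 16 male rats, 4 given saline and 4 each given 10, 20 or 40 mg/kg xylazine for 28 days, per the labels' protocols. Every library came from a separate animal, so replicates are animals and p-values for single genes measure the spread between animals. No batch, date or sequencing lane was given, and replicate numbers were not taken to pair animals across groups.

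The deposited table gave 4 kinds of value per library for 17544 genes. The authors deposited estimates called expected counts, which are estimated reads per gene. They had no normalization, and between 92.2% and 93.0% of the values in each library were whole numbers. The authors also deposited FPKM, fragments scaled by transcript length and library size, and TPM, transcripts scaled to a common total. The fourth kind, normalized read counts, is a signal that the authors deposited and that equals the expected counts multiplied by 1 factor per library. How that factor was made was not stated. Per the submitters' processing notes, Bowtie2, RSEM, DESeq2 and the rat genome build mRatBN7.2 were used, with no versions, roles, read filters or strandedness stated. No reference genome accompanied the table, so genes were identified by symbol and NCBI gene number and no coordinates are given. Of the 17544 gene numbers, 17324 were found in a RefSeq gene table, and 17104 were protein coding. The 16 columns of averages and the normalized read counts were not used for any test.

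The deposited counts summed to between 16059900 and 16956900 per library. They were rounded to whole numbers before fitting. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 12732 genes, 702 of them with placeholder symbols. Counts scaled to a common library total (CPM) were computed in edgeR 4.0.16 under R 4.3.3 with trimmed mean of M values (TMM) factors, which ranged from 0.924 to 1.10. Group values are means with SD over 4 animals. Quasi-likelihood negative binomial models (edgeR, robust) with 1 term per group gave the dose comparisons and a test of any dose against saline. A further model with dose as a number gave a linear trend, expressed as the log2 change over the whole range from saline to 40 mg/kg. Log2 fold changes are given with standard errors (SE). For single genes the SE was derived from the test, as the absolute log2 fold change divided by the square root of F. All tests were two-sided unless stated, and p was adjusted by the Benjamini-Hochberg method over all genes tested in each comparison, with 0.05 as the threshold. The principal component plane used log2 CPM with a prior count of 2.

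From 45 gene lists, the 41 with at least 5 members tested were compared with all other genes by camera (limma 3.58.1) at a preset correlation of 0.01 and at an estimated correlation. Its p was adjusted over the lists of a comparison. The rotation test fry, which asks whether the genes of a list move on balance in 1 direction and not whether they differ from other genes, was run beside it. For each list, genes were also counted after the adjustment was made within that list. Agreement between doses was measured as a correlation across genes and set against 100 simulations in which doses shared nothing but the saline animals.

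The comparisons, lists, alternatives and the rule for naming genes were fixed before the data were examined. For each dose against saline, the rule named the 10 higher and 10 lower genes with the largest change among those passing, with a mean of at least 5 CPM in a group and no overlap between the 4 treated and 4 saline animals. For the trend it named the 10 higher and 10 lower genes with the smallest p. Where none passed, it named the 5 with the smallest p. It also named up to 4 members of each list that passed in any comparison, and a set of genes fixed in advance in any case. A few genes that the rule names are not reported here. Genes named outside the rule are described as chosen after their values were seen.

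The alternatives were DESeq2 size factors, total count scaling, no filter, a stricter filter (5 CPM in 4 libraries), DESeq2 1.42.0 and limma-voom as the test, limma on log2 TPM with 1 or 0.1 added and on log2 FPKM with 1 added (at least 1 TPM or FPKM in 4 libraries), and a block for the replicate number. Further ones were a fit of the compared groups alone, a minimum absolute log2 fold change of 1, an adjusted p under 0.1, dose as its rank, a trend among the 3 xylazine doses, and leaving out each library in turn. The removal of 2 libraries together was chosen after seeing the data. The model was tested on simulated data with the design and depth of the study. For 40 mg/kg against saline it recovered 41.8% of genes changed by 1.5 times, 67.2% of those changed by 2 times and 92.4% of those changed by 4 times, and called 4 of 12506 unchanged genes. It called 11 of 12506 for 40 against 20 mg/kg and 5 for 40 against 10 mg/kg. Of 12732 unchanged genes it called 1 for 10 mg/kg against saline, 0 for 20 mg/kg against saline and 1 for 20 against 10 mg/kg.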

Results

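The livers of male rats were sequenced after 28 days of injections with saline or with xylazine, a veterinary sedative that acts on adrenergic receptors. Xylazine was given at 10, 20 or 40 mg/kg, with 4 animals in each of the 4 groups and 16 libraries in all. Library totals of expected counts lay between 16513400 and 16956900 for saline, between 16236200 and 16828800 for 10 mg/kg, between 16511300 and 16942600 for 20 mg/kg, and between 16059900 and 16859600 for 40 mg/kg. The 10 most abundant genes took 24.0 to 28.5% of the counts of a library. On the first principal component of 12732 genes, which held 14.8% of the variance, the 40 mg/kg animals lay between 18.0 and 24.3. Saline animals lay between -21.7 and -4.54 and those given 10 mg/kg between -17.7 and -4.68. The 20 mg/kg animals reached from -7.24 to 14.8.

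The comparison of 40 mg/kg with saline asked which liver genes change at the highest dose, in a study whose stated subject is liver injury by xylazine. Genes of fatty acid and triglyceride synthesis were higher. Srebf1 (gene 78968), which encodes the transcription factor that switches on lipogenic genes, rose from 183 ± 44.7 CPM in saline to 462 ± 73.6 CPM (SD, n = 4 each), a log2 fold change of 1.34 (SE 0.189, adjusted p = 0.00589). Its 4 treated animals lay between 383 and 543 CPM and its saline animals between 139 and 236 CPM. Fasn (gene 50671), the fatty acid synthase, rose from 289 ± 73.0 to 771 ± 377 CPM, a log2 fold change of 1.41 (SE 0.294, adjusted p = 0.0385). Scd (gene 246074), which desaturates stearoyl-CoA, rose from 1702 ± 423 to 5510 ± 1395 CPM (log2 1.69, SE 0.373, adjusted p = 0.0466). Me1 (gene 24552), the malic enzyme that supplies NADPH for lipid synthesis, rose from 69.5 ± 16.7 to 190 ± 78.4 CPM (log2 1.45, SE 0.241, adjusted p = 0.0150). Pnpla3 (gene 362972), a lipid droplet protein whose human counterpart carries a fatty liver risk variant, rose from 21.6 ± 12.3 to 182 ± 107 CPM (log2 3.07, SE 0.601, adjusted p = 0.0332). The fatty acid desaturase Fads2 rose by a log2 fold change of 0.80 (adjusted p = 0.0200) and Scd2 by 0.77 (adjusted p = 0.0424). In each of these 7 genes all 4 treated animals lay above all 4 saline animals. That adds little to the calls, since 140 of the 141 genes passing showed no overlap. For Pnpla3 and Scd the rule for naming genes also asked for it. Acaca (log2 0.54, adjusted p = 0.0748), Acly (0.85, adjusted p = 0.0957) and Elovl6 (1.38, adjusted p = 0.119), chosen after their values were seen as further enzymes of the pathway, did not pass. Of the 20 list members 19 were positive and Lpin1, at a log2 fold change of -1.94 (adjusted p = 0.167), was the 1 negative member. The list median was 0.68. Over all genes 7 members passed, and 17 higher and 1 lower passed when adjusted over the list alone. Camera gave an adjusted p of 1.76e-13 at the preset correlation and 0.0166 at the estimated correlation. The call of Srebf1 held without any single library. That of Me1 ended without saline replicate 1 (adjusted p = 0.0522), and those of Pnpla3, Fasn and Scd ended in 5, 9 and 13 of the 16 removals, with adjusted p of at most 0.0882, 0.0971 and 0.114. Fads2 lost its call in 3 removals and Scd2 in 12 (adjusted p of at most 0.0647 and 0.0882).

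**Figure D1:**
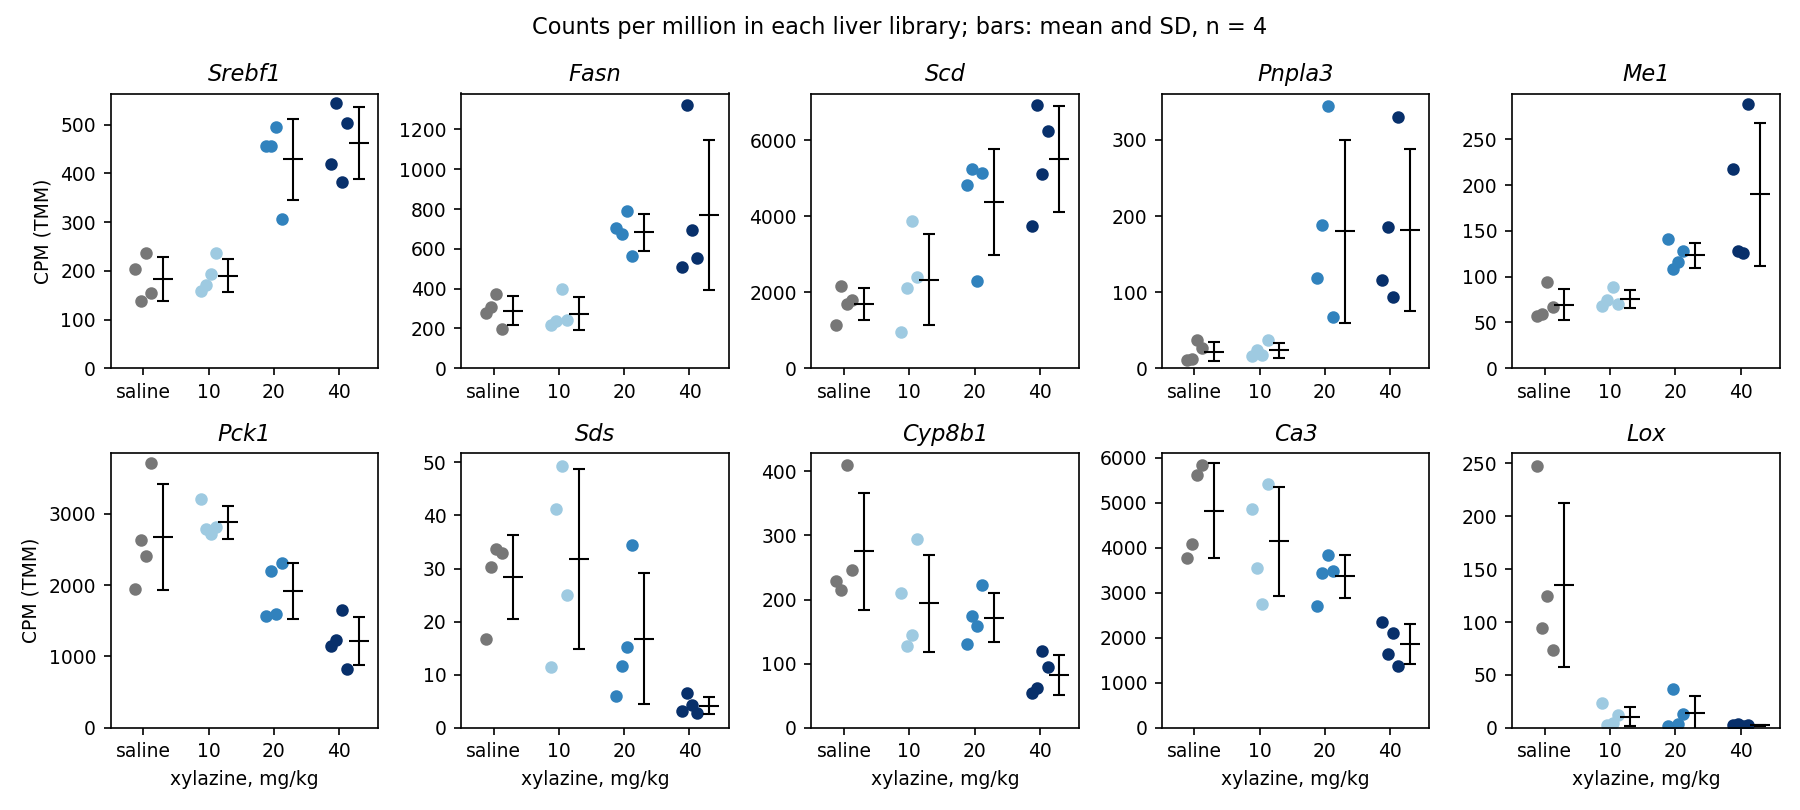
CPM of 10 genes in each library by group, with TMM scaling. Points are animals and bars show the mean and SD of 4 animals; Srebf1 lay between 139 and 236 CPM in saline and between 383 and 543 CPM at 40 mg/kg.

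Single genes of gluconeogenesis, amino acid catabolism and bile acid synthesis were lower at 40 mg/kg. Pck1 (gene 362282), which encodes the committed enzyme of gluconeogenesis, fell from 2672 ± 746 to 1215 ± 337 CPM, a log2 fold change of -1.14 (SE 0.211, adjusted p = 0.0200). Sds (gene 25044), the serine dehydratase, fell from 28.4 ± 7.96 to 4.20 ± 1.68 CPM (log2 -2.76, SE 0.571, adjusted p = 0.0424). Got1 (gene 24401), the cytosolic aspartate aminotransferase, fell from 157 ± 23.6 to 62.0 ± 8.88 CPM (log2 -1.34, SE 0.240, adjusted p = 0.0200). Cyp8b1 (gene 81924), the enzyme that sets the share of cholic acid, fell from 275 ± 91.1 to 82.5 ± 30.7 CPM (log2 -1.74, SE 0.323, adjusted p = 0.0240). Cyp7a1, which starts bile acid synthesis, did not pass (log2 0.74, SE 0.643, adjusted p = 0.621). The bile acid list, in which 1 gene passed higher and 1 lower over all genes and 2 higher and 3 lower when adjusted over the list alone, was not called (camera adjusted p = 0.965), with a median of 0.07 and a mean of -0.05. Nor was the gluconeogenesis list, in which 15 of 21 genes were negative and 2 passed, both lower, over all genes and when adjusted over the list alone (median -0.05, camera adjusted p = 0.280). Of the 26 members of the urea cycle and amino acid catabolism list 25 were negative, with a median of -0.25. Of these members 2 passed over all genes and 5 passed when adjusted over the list alone, all lower. Camera gave an adjusted p of 4.14e-07 for this list, and 0.521 with an estimated correlation. Of 14 genes typical of periportal hepatocytes 11 were negative, with a median of -0.24. There 2 passed over all genes and 7 passed when adjusted over the list alone, all lower, and camera gave an adjusted p of 0.0035 (0.521 as the adjusted p with an estimated correlation). Got1 and Cyp8b1 each lost their call without saline replicate 1 and without xylazine 40 replicate 1, 2 or 4, at adjusted p of at most 0.0685 and 0.0664. Pck1 lost it without xylazine 40 replicate 1 (adjusted p = 0.0590) or 4 (adjusted p = 0.0578), and Sds in 10 of the 16 removals (adjusted p of at most 0.118).

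The largest fall among the genes passing at 40 mg/kg was that of Lox (gene 24914), a copper enzyme that crosslinks collagen, which went from 135 ± 77.8 CPM in saline to 2.56 ± 0.444 CPM at 40 mg/kg (log2 -5.72, SE 0.969, adjusted p = 0.0200). Lox stood at 10.7 ± 9.20 CPM at 10 mg/kg and 13.9 ± 16.01 CPM at 20 mg/kg. Ca3 (gene 54232), a carbonic anhydrase of liver and muscle, fell from 4825 ± 1050 to 1864 ± 442 CPM (log2 -1.37, SE 0.222, adjusted p = 0.0129). Mcm10 (gene 307126), a replication factor, fell from 13.7 ± 5.27 to 3.01 ± 0.252 CPM (log2 -2.18, SE 0.338, adjusted p = 0.0129). Zbtb16, a glucocorticoid-induced transcription factor, fell from 37.4 ± 24.6 to 5.15 ± 1.87 CPM (log2 -2.86, adjusted p = 0.0321). RT1-CE13, an MHC class I gene, fell from 34.9 ± 13.5 to 8.40 ± 2.36 CPM (log2 -2.05, SE 0.397, adjusted p = 0.0289). Tenm2 fell by 2.64 and Exph5 by 1.48 on the log2 scale (adjusted p = 0.0244 and 0.0485). Among higher genes, Aldh1a1, a retinal dehydrogenase, rose from 41.3 ± 19.4 to 142 ± 74.4 CPM (log2 1.78, adjusted p = 0.0440), and Kbtbd12 and Kcnk5 rose by log2 fold changes of 2.45 and 1.73, as did Otub2 (adjusted p = 0.0344) and Kifc3 (adjusted p = 0.0436) by less. Ca3 and Mcm10 kept their calls without any single library. Lox lost it without saline replicate 1 or any 1 of the 4 libraries of 40 mg/kg (adjusted p of at most 0.0683). Of the 16 removals, Aldh1a1 lost its call in 13, Kbtbd12 in 12, Exph5, Kcnk5 and Kifc3 in 11 each, and Otub2 in 7. RT1-CE13 and Tenm2 lost theirs in 6 each and Zbtb16 in 5, and over these 9 genes the adjusted p was at most 0.119. Exph5 also lost its call in 9 of 12 other alternatives, with log2 fold changes between -1.51 and -0.78, and Aldh1a1 in 3.

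In all, 141 genes passed at 40 mg/kg, 60 higher and 81 lower, and 43 of them changed by a log2 fold change of at least 1. For 140 of the 141, no treated animal overlapped a saline animal, as in 1184 of the genes tested, where chance gives 2.86%. At an unadjusted p under 0.05 there were 2063 genes, against 636.6 by chance. DESeq2 called 517, including the 141, and limma-voom 138. Total count scaling gave 141 genes split as 91 higher and 50 lower, and limma on TPM with 1 added gave 122 higher and 45 lower. FPKM gave 89 higher and 56 lower. The count was 27 without saline replicate 1, 72 without saline replicate 2 and 70 without saline replicate 4. It was 63, 78, 57 and 29 without xylazine 40 replicates 1, 2, 3 and 4. Leaving out xylazine 20 replicate 3 and xylazine 40 replicate 4 together, chosen after the data were seen, gave 51. For the doses against saline and the trend, 90 results for named genes passed and 59 of them lost their call without at least 1 library. The number lost was 45, 34, 20 and 40 without saline replicates 1 to 4, and 3, 12, 17 and 24 without those of 10 mg/kg. It was 21, 22, 6 and 4 without those of 20 mg/kg, and 42, 34, 31 and 53 without those of 40 mg/kg. None of the 90 changed direction under any alternative.

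**Figure D2:**
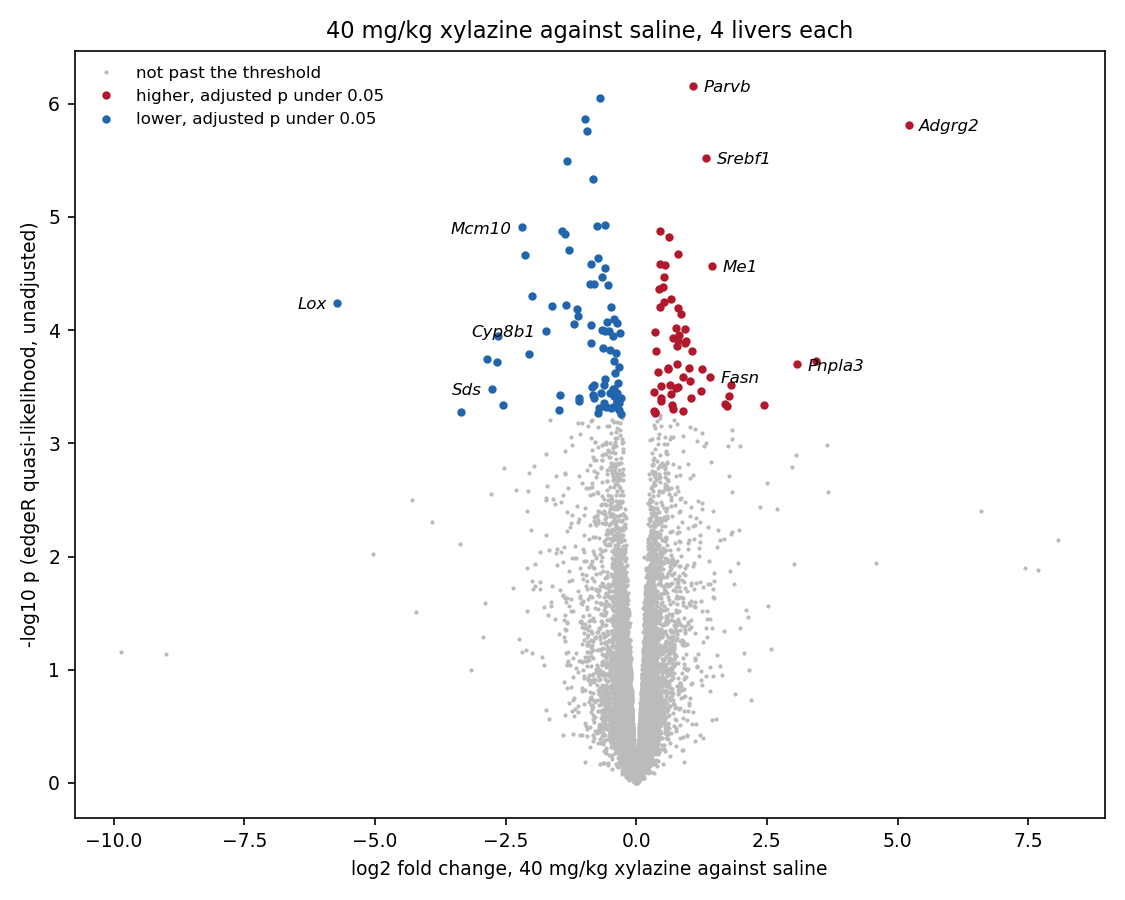
Log2 fold change at 40 mg/kg against saline and the negative log10 of the unadjusted p for 12732 genes. Red points are the 60 genes higher and blue points the 81 genes lower at an adjusted p under 0.05, and grey points are the other genes.

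Camera called 11 lists at 40 mg/kg, 8 higher and 3 lower, of which the fatty acid synthesis list alone held with an estimated correlation. The 5 lists given next had medians between 0.09 and 0.27. Among 28 genes of fatty acid oxidation 18 were positive, with a median of 0.20 and a camera adjusted p of 0.000541 (0.521 as the adjusted p with an estimated correlation). The peroxisomal enzyme Ehhadh rose by 0.76 (adjusted p = 0.0240) and the lipid droplet coat gene Plin2 by 0.69 (adjusted p = 0.0466), and 9 members passed when adjusted over the list alone. Cpt1a, the carrier enzyme of mitochondrial oxidation, did not pass (log2 -0.41, adjusted p = 0.519), nor did Pdk4 (adjusted p = 0.998). Of 82 ribosomal protein genes 77 were positive, with a median of 0.16 (camera adjusted p = 3.19e-08, adjusted p with an estimated correlation = 0.598), and Rpl22l1 alone passed over all genes or when adjusted over the list alone (log2 0.78, adjusted p = 0.0332). Of 47 nuclear genes of the respiratory chain 41 were positive, with a median of 0.09 (camera adjusted p = 0.000623, and 0.610 as the adjusted p with an estimated correlation), and Atp5mc1 alone passed (log2 0.43, adjusted p = 0.0177). Of 24 genes induced through the receptors CAR and PXR 19 were positive, with a median of 0.27. There 1 passed over all genes and 4 passed when adjusted over the list alone, with a camera adjusted p of 0.00528 (0.521 as the adjusted p with an estimated correlation). The reporter genes of these receptors, Cyp2b1 (log2 0.22, adjusted p = 0.904) and Cyp3a2 (log2 0.05, adjusted p = 0.962), did not pass. Among 18 targets of the oxidant sensor NRF2 13 were positive, with a median of 0.25, 2 passing over all genes and 3 passing when adjusted over the list alone (camera adjusted p = 0.0132, adjusted p with an estimated correlation 0.521). Tkt rose by 0.52 (adjusted p = 0.0200) and Abcc4 by 0.71 (adjusted p = 0.0480). Of the 16 removals, Abcc4 lost its call in 13, Plin2 in 12, Rpl22l1 in 6, Ehhadh in 5, and Atp5mc1 and Tkt in 3 each. Abcc4 also lost it in 6 of 12 other alternatives and Plin2 in 5. Nqo1 (log2 -0.24, adjusted p = 0.897) and Hmox1 (log2 -0.03, adjusted p = 0.961) did not pass. Of 25 cholesterol synthesis genes 15 were negative, with a median of -0.08, and none passed over all genes or when adjusted over the list alone. The drug-metabolizing genes Cyp2c11 (log2 0.11, adjusted p = 0.799) and Cyp1a2 (log2 -0.85, adjusted p = 0.203) did not pass. Neither did the growth factor gene Igf1 (log2 -0.24, adjusted p = 0.427) or the growth factor binding protein gene Igfbp1 (log2 0.83, adjusted p = 0.569).

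In the lists closest to liver injury few genes passed over all genes at 40 mg/kg, which does not show that the lists were unchanged. Alb, the albumin gene, did not pass (log2 -0.02, SE 0.121, adjusted p = 0.954), and of 16 hepatocyte genes 12 were negative with a median of -0.08 and none passing. Among 22 acute phase genes 11 were positive and 11 negative, with a median of -0.03, and Crp did not pass (log2 -0.30, adjusted p = 0.181). The injury marker Lcn2 did not pass (log2 -0.27, adjusted p = 0.879), and its value depended on single libraries, at 0.36 without saline replicate 4 and -1.11 without xylazine 40 replicate 2. Of 16 inflammatory genes 11 were negative, with a median of -0.14, and of 27 interferon-induced genes 24 were negative, with a median of -0.20, and no member of these lists passed over all genes or when adjusted over the list alone. Of 20 targets of p53 none passed over all genes, and 1 higher and 3 lower passed when adjusted over the list alone. Of 22 genes of the unfolded protein response none passed over all genes, and 4 higher and 3 lower passed when adjusted over the list alone; its median was -0.03 and its mean 0.28. Among 14 heat shock genes Bag3 fell by 0.81 on the log2 scale (adjusted p = 0.0442). For the fibrosis and extracellular matrix list the median was 0.17 but the mean was -0.10, since Lox lay far below the rest. Camera placed this list higher (adjusted p = 0.0182, and 0.521 as the adjusted p with an estimated correlation). The basement membrane gene Col4a2 rose by 0.48 (adjusted p = 0.0423), and 7 higher and 1 lower passed when adjusted over the list alone. Col4a2 lost its call in 9 of the 16 removals and Bag3 in 10. Of 12 other alternatives, Bag3 also lost it in 8 and Col4a2 in 1. Col1a1 (log2 0.05, adjusted p = 0.969, and 0.43 without saline replicate 4) and Timp1 (log2 0.68, SE 0.207, adjusted p = 0.109) did not pass. For none of these lists except the fibrosis list did camera pass.

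Markers of other cells were measured beside these groups. All 10 mesothelial markers were positive at 40 mg/kg, with a median of 1.07 and none passing (camera adjusted p = 0.0031, adjusted p with an estimated correlation 0.521). Their mean log2 level lay 1.25 above the saline mean in saline replicate 1 and -1.04 in saline replicate 3. In the 40 mg/kg animals it was 1.79, 0.21, 1.59 and 0.95. Of 29 cell cycle genes 23 were negative, with a median of -0.65 and none passing (camera adjusted p = 0.00702, adjusted p with an estimated correlation 0.737). Markers of Kupffer cells (median 0.06), endothelium (0.20), stellate cells (0.27) and cholangiocytes (-0.13) were not called. For Kupffer cells the mean was -0.01, and for cholangiocytes camera leaned higher against a negative median and mean. Of the adrenergic receptors, through which xylazine acts, Adra2a was not tested, with 0 to 3 expected counts per library and 0 in 13 of 16. At this depth no difference in Adra2a was detectable. Adra2b (log2 0.51, adjusted p = 0.409) and Adra1b (log2 -0.13, adjusted p = 0.636) did not pass, and 17 of 22 genes of adrenergic and cAMP signalling were negative with 0 passing over all genes and 1 lower passing when adjusted over the list alone.

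**Figure D3:**
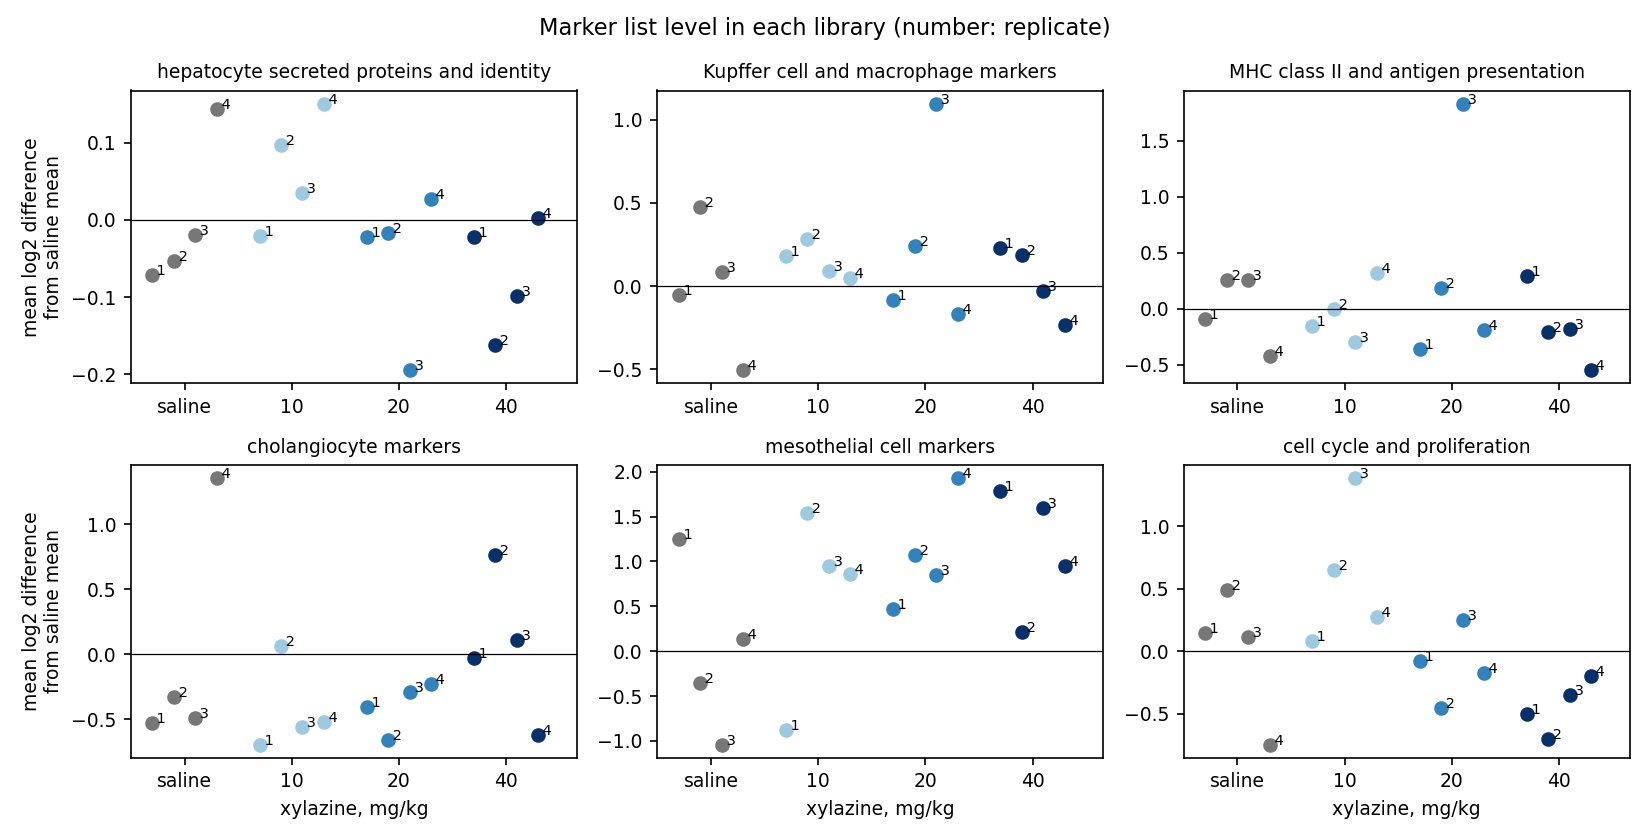
Mean log2 difference from the saline mean of 6 gene lists in each of the 16 libraries. Each number is a library with its replicate number; MHC class II genes lay 1.83 above the saline mean in xylazine 20 replicate 3.

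The comparison of 20 mg/kg with saline asked the same of the middle dose. The fatty acid synthesis list was higher here too, with 19 of 20 members positive and a median of 0.64. None passed over all genes and 15 passed when adjusted over the list alone, all higher. Camera gave an adjusted p of 5.74e-18 and 0.00487 with an estimated correlation. Srebf1 stood at 428 ± 82.9 CPM against 183 ± 44.7 CPM in saline (n = 4 each), a log2 fold change of 1.23 that missed the threshold (adjusted p = 0.0741). Pnpla3 stood at 180 ± 120 CPM (log2 3.06, adjusted p = 0.193). Baiap2l1, an actin regulator, had a log2 fold change of -0.81 (adjusted p = 0.0741), and the adhesion gene Parvb one of 0.72, Osbpl11 one of 0.93 and Fads2 one of 0.76 (adjusted p = 0.193 each). In edgeR 0 genes passed, with 1162 at an unadjusted p under 0.05 against 636.6 by chance. DESeq2 called 51 (26 higher and 25 lower), limma-voom 0 and limma on TPM 2. Without xylazine 20 replicate 4 the count was 19, without saline replicate 3 it was 3, and it was 1 without saline replicate 4 or without xylazine 10 replicate 1. Camera called 9 other lists, each with an adjusted p of 0.802 at the estimated correlation. Among them all 10 mesothelial markers were positive with a median of 1.09 and none passing (adjusted p = 0.00176). The 20 mg/kg animals lay 0.47, 1.07, 0.85 and 1.93 above the saline mean in that list, and the saline animals ranged from -1.04 to 1.25. All 16 Kupffer cell and macrophage markers were positive with a median of 0.29 (adjusted p = 0.0261), and this list lost its call under total count scaling. In that list xylazine 20 replicate 3 lay 1.10 above the saline mean. Of 26 genes of amino acid catabolism 23 were negative, with a median of -0.14 (adjusted p = 0.0106).

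The comparison of 10 mg/kg with saline asked whether the lowest dose changes liver genes. Cell cycle genes were higher on average, with 28 of 29 positive and a median of 0.67 (camera adjusted p = 1.99e-12), and so were immediate early genes, with 17 of 18 positive and a median of 0.87 (camera adjusted p = 1.95e-06). Neither held with an estimated correlation (adjusted p = 0.592 for both), nor did any of the 13 lists that camera called here, 10 higher and 3 lower. Animals of this group differed widely in both. Xylazine 10 replicate 3 lay 1.38 above the saline mean in cell cycle genes and 1.64 in immediate early genes, while replicate 1 lay at 0.08 and -0.41. Of 25 cholesterol synthesis genes 24 were negative, with a median of -0.16 (camera adjusted p = 3.53e-06, adjusted p with an estimated correlation 0.592). Fatty acid synthesis genes were not called, with 12 of 20 positive and a median of 0.04. Cdca5 (log2 1.79, SE 0.345), Gtpbp4 (-0.54), Smc6 (-0.40) and Lrrc42 (0.37) had the smallest p of the comparison together with Adgrg2, and none passed (adjusted p = 0.999 each). Adgrg2 stood at 0.561 ± 0.171 CPM against 0.0439 ± 0.0556 CPM in saline. In edgeR 0 genes passed, and the 509 at an unadjusted p under 0.05 were fewer than the 636.6 that chance gives. DESeq2 and limma-voom called 0, and 1 gene passed without saline replicate 4.

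**Figure D4:**
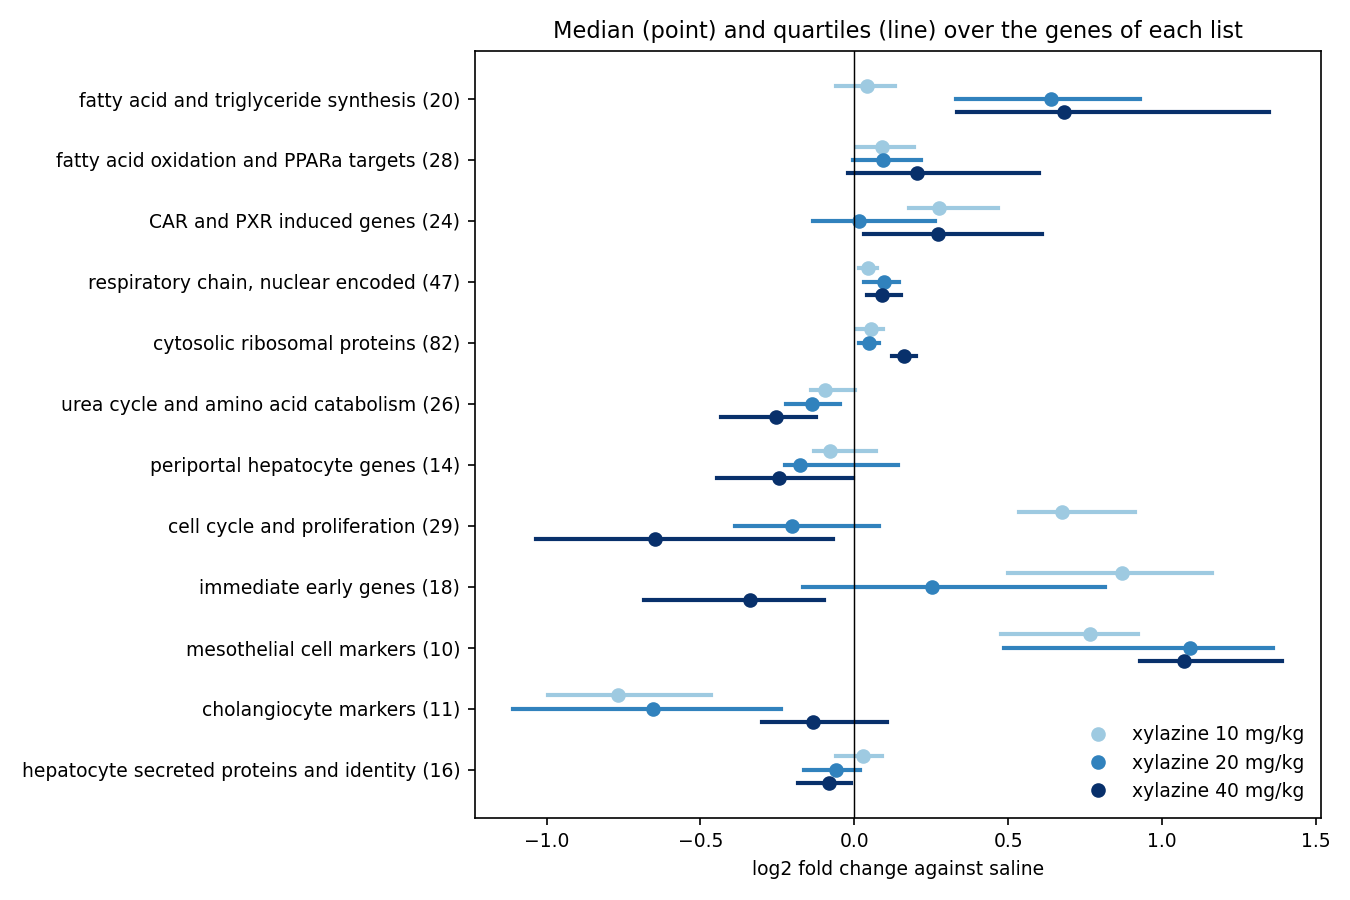
Median log2 fold change against saline of 12 gene lists at 10, 20 and 40 mg/kg. Points are medians over the members tested and lines reach from the lower to the upper quartile; the fatty acid synthesis list lay at 0.04, 0.64 and 0.68.

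Direct comparisons between doses asked whether one dose differs from another. Between 10 and 40 mg/kg, Srebf1 rose by a log2 fold change of 1.28 (adjusted p = 0.0106), Me1 by 1.33 (adjusted p = 0.0360) and Fasn by 1.49 (adjusted p = 0.0465). Pck1 fell by 1.24 (adjusted p = 0.0200) and Zbtb16 by 3.69 (adjusted p = 0.0179) on the log2 scale. In all 46 genes passed, 14 higher and 32 lower at 40 mg/kg, and 30 of them were among the 141, which rest on the same 40 mg/kg animals. The fatty acid synthesis list was higher at 40 than at 10 mg/kg, with a median of 0.57 and a camera adjusted p of 2.22e-14, and 0.0139 as the adjusted p with an estimated correlation. DESeq2 called 286 genes. Total count scaling gave 22 higher and 15 lower, limma on TPM with 1 added 51 higher and 18 lower, and FPKM 32 higher and 21 lower. Leaving out xylazine 10 replicates 1, 2, 3 and 4 gave 120, 2, 24 and 25 genes, leaving out xylazine 20 replicate 2 gave 20, and leaving out xylazine 40 replicates 1, 2, 3 and 4 gave 5, 10, 15 and 12. Between 10 and 20 mg/kg the fatty acid synthesis list was higher at 20, with a median of 0.50 (camera adjusted p = 1.73e-17, adjusted p with an estimated correlation 0.00549). No gene passed in edgeR there, with 985 at an unadjusted p under 0.05. Srebf1 came closest (log2 1.17, adjusted p = 0.0546). DESeq2 called 34 genes and limma-voom 0. Without saline replicate 1 there were 3, without saline replicate 3 or xylazine 20 replicate 4 there were 6, and without xylazine 10 replicate 2 there was 1. Between 20 and 40 mg/kg 0 genes passed in edgeR, with 688 at an unadjusted p under 0.05 and a smallest adjusted p of 0.420. DESeq2 called 7 and limma-voom 0, and 1 passed without xylazine 10 replicate 4. A fit of these groups alone called 1 gene, lower at 40 mg/kg.

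The dose trend asked for which genes a straight line over dose had a slope, a test that a change already complete at a low dose can also pass. Parvb (gene 362973), an adhesion protein, rose over the dose range, from 9.01 ± 1.14 CPM in saline through 10.7 and 14.8 to 19.2 ± 3.43 CPM (log2 1.12, SE 0.133, adjusted p = 0.00154). Mgll, which splits monoacylglycerols, rose from 71.2 ± 2.34 to 125 ± 16.08 CPM (log2 0.82, adjusted p = 0.00607). Fam126b fell by 1.04 on the log2 scale (adjusted p = 0.00241), and Nlrp12, an inhibitor of inflammatory signalling, fell from 192 ± 34.2 to 76.5 ± 17.4 CPM (log2 -1.41, adjusted p = 0.00284). Ca3, Mcm10, Me1, Srebf1, Pck1, Got1, Cyp8b1 and Lox also passed. These 12 genes kept their call without any single library. Among the 3 xylazine doses alone, Fam126b, Mcm10, Nlrp12 and Pck1 passed and the other 8 did not. Most of the fall of Lox lay between saline and 10 mg/kg, and its slope among the xylazine doses was -2.25 (adjusted p = 0.428). Further genes by smallest p were Mrps34, Atp5mc1, Lpcat3, Dnajc11, Mcrip2, App and Tmem135, higher by log2 0.39 to 0.76, and Rnd2, Cflar, Fmo4, Rnf138, Banp and Zfp764, lower by -1.42 to -0.62, at adjusted p of at most 0.0112. Of the urea cycle genes, Cps1 (log2 -0.43, adjusted p = 0.0451) and Asl (log2 -0.49, adjusted p = 0.0310) fell with dose. In the clock list Hlf (log2 0.63, adjusted p = 0.0220) and Cry1 (0.75, adjusted p = 0.0444) rose and Nr1d1 fell (-2.32, adjusted p = 0.0449). Hlf lost its call without xylazine 40 replicate 1 (adjusted p = 0.0509), while Cry1 and Nr1d1 lost theirs in 11 and 12 of the 16 removals, Cps1 in 13 and Asl in 5. Of 13 other alternatives, Cps1 also lost its call in 8, Asl in 6 and Cry1 in 4. The amino acid synthesis genes Asns, Phgdh and Psat1 passed at 2.34, 3.34 and 2.61, and without xylazine 40 replicate 4 they fell to 1.02, 1.63 and 0.98 and no longer passed. Without the same library Abcc3, a bile acid exporter, went from 1.27 to 0.58, and Gsta3, a glutathione transferase, from 1.64 to 0.997, and neither passed. Their calls also ended without other libraries, in 6 of the 16 removals for Asns, 9 for Phgdh, 12 for Psat1, 7 for Abcc3 and 13 for Gsta3. Other list members that rose with dose were Gclc (0.76), Acot3 (0.81), Cpt2 (0.54), Axin2 (0.75) and Pdgfrb (0.44). Those that fell were Mup4 (-0.82), Mup5 (-0.73), Dnajb9 (-0.58), Cidec (-0.45), Mcl1 (-0.35) and Prkar1a (-0.23), at adjusted p of at most 0.0467 over both sets. Of these 11, Mup4 alone kept its call in all removals, and Gclc lost its call without xylazine 40 replicate 4 alone.

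In all 371 genes passed in the trend, 163 higher and 208 lower, with 2391 at an unadjusted p under 0.05. DESeq2 called 750. Of the 141 genes found at 40 mg/kg 138 were among the 371, but both fits use the same saline and 40 mg/kg animals, so the overlap is no separate evidence. Total count scaling gave 276 higher and 112 lower, limma on TPM with 1 added 400 and 84, and FPKM 218 and 84. Among the 3 xylazine doses alone, a fit with fewer animals and a narrower dose range, 14 genes passed. The count was 172 and 179 without saline replicates 2 and 4, and 193, 227, 220 and 127 without xylazine 40 replicates 1, 2, 3 and 4. The fatty acid synthesis list had a median of 0.77 in the trend, and 9 members passed over all genes. Camera gave an adjusted p of 4.5e-13 for it, and 0.174 as the adjusted p with an estimated correlation, so its call in the trend depended on the correlation assumed. Fry, which does not compare a list with other genes, gave an adjusted p of 0.00168 there, and 0.000312 and 0.000140 at 20 and 40 mg/kg against saline, and called no other list in any of these 3. A test of any dose against saline called 46 genes. That count was 26, 22 and 23 without saline replicates 1, 2 and 4, and 17, 25 and 19 without xylazine 10 replicates 2, 3 and 4. It was 21, 17 and 89 without xylazine 20 replicates 1, 2 and 4, and 6, 8, 15 and 9 without xylazine 40 replicates 1, 2, 3 and 4.

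Changes at different doses were compared across the 12732 genes, which are not independent replicates. The correlation of the log2 fold changes at 20 and 40 mg/kg was 0.667. Simulated doses that shared nothing but the saline animals gave a mean of 0.501 and at most 0.541. With the saline animals split 2 and 2, so that each dose had its own controls, the correlation was 0.262. The values for 10 and 20 mg/kg were 0.498, against 0.496 in simulation and 0.0221 with split controls. Those for 10 and 40 mg/kg were 0.413, against 0.4995 and 0.0132. Of the 141 genes changed at 40 mg/kg 125 (88.7%) went the same way between 10 and 20 mg/kg, a comparison with no animal in common with theirs. Random sets of genes gave a mean of 49.8% and at most 64.5%. Both the simulations and the random sets treated genes as independent. Genes that move together can spread wider, so neither range gives a test of chance. The correlation of 0.413 for 10 and 40 mg/kg itself lay below the simulated mean by more than the simulated SD of 0.0180.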

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

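Among the tests below, those of the hepatocyte share, of time of day or feeding, of the 3 sources of MHC class II signal and of haplotype were chosen only after the result was seen.

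The fatty acid synthesis list was higher at 20 and 40 mg/kg, with a median of 0.68 at 40 mg/kg. Total count scaling gave a median of 0.75. Under it the median over all genes at 40 mg/kg was only 0.0625, too small a shift to undo the rise of the list. This argues against the choice between the 2 scalings as the source and tests no more than that. The highest of 16 hepatocyte genes stood at 0.34, which argues against a larger share of hepatocytes. Time of day or feeding at sampling remains open, since 4 of 18 clock genes followed dose where 0.525 would by chance (one-sided Fisher exact p = 0.00157). That count is fragile, as Hlf lost its trend without xylazine 40 replicate 1 and Cry1 and Nr1d1 lost theirs in 11 and 12 of 16 removals. The Fisher test also treated genes as independent, and clock genes that move together can raise such a count. Its p therefore does not measure the spread between animals. An effect of xylazine on lipid synthesis is the hypothesis the design gives, and it may act together with feeding or timing, which no label records.

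MHC class II genes stood apart in xylazine 20 replicate 3, where 8 of them lay 2.61 (SE 0.112) above the mean of the other 3 animals on the log2 scale. The rule for singling out libraries, given below, flagged no list in this animal, so this pattern did not come from that rule. Each SE in this paragraph is over the genes of a list in 1 animal and does not measure the spread between animals. Fewer hepatocytes would raise all other cell types alike, but endothelial, stellate and cholangiocyte markers together lay -1.25 (SE 0.179) from the macrophage markers. Erythroid markers at -0.85 (SE 0.291) argue against blood in the tissue, and B cell markers, whose rise lay -2.36 (SE 0.403) from that of the MHC class II genes, argue against spleen or lymph node. Macrophage markers were higher by 1.10 (SE 0.167) and T and NK cell markers by 1.04 (SE 0.142), less than the MHC class II genes. The 4 neutrophil and monocyte markers at 1.19 (SE 0.785) lay within 2 SE of 0. The 27 interferon-induced genes were also higher, by 0.85 (SE 0.165). Immune cells in this liver may be the source, and 1 animal cannot tie them to the dose. No biological explanation was tested.

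RT1-CE13 fell at 40 mg/kg by 2.05 and RT1-CE12, chosen after its values were seen, by 2.55 on the log2 scale, and these are MHC class I genes with many near-identical relatives. Another haplotype in outbred animals would split the animals of a group into high and low ones. The largest gap took a share of 0.146 of the range, but across all doses together. Differences between doses can fill that range, so this test cannot decide on haplotype, which remains open. In saline, replicates 1 and 2 stood at 42.4 and 49.7 CPM in RT1-CE13 and at 7.17 and 5.51 CPM in RT1-CE12. Saline replicates 3 and 4 were lower in both, at 20.3 and 27.1 CPM and at 1.99 and 2.51 CPM. At 40 mg/kg the order of the animals differed between the 2 genes. Reads shared between relatives cannot be told apart from lower expression for these 2 genes. What keeps it open is that the summed counts of 31 class I genes changed by a log2 of -0.69 (SE 0.328) while 4 of 17 abundant ones were higher. Those 4 were RT1-N2 at 0.81 (SE 0.547), RT1-N3 at 0.60 (SE 0.345), RT1-CE16 at 0.26 (SE 0.516) and RT1-T24-3 at 0.10 (SE 0.418). Each lay within 2 SE of 0 and none passed, so their rise is uncertain, and the rest of the 17 were lower. An effect of xylazine on class I genes is the hypothesis of the design, and it was not tested separately.

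A library was singled out when its gap to the nearest of the other 3 in its group took most of the range of the group. Chance flags about 1 in 20 groups, and 31 of 372 gene groups were singled out against 18.6 by chance, and 9 of 176 list groups against 8.8. By library, 8 genes pointed to xylazine 40 replicate 4 and 3 each to xylazine 20 replicates 1 and 3, and no explanation was tested for those below.

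In xylazine 40 replicate 4, genes of serine and asparagine synthesis stood highest. Asns was at 39.9 CPM against 4.72 to 6.87 in the other 3 animals, Phgdh at 41.3 against 0.649 to 6.46 and Psat1 at 51.2 against 3.72 to 9.92. Abcc3 was at 13.8 CPM (3.87 to 4.19 in the others), Adgrg2 at 3.56 (1.29 to 1.65), Tkt at 345 (270 to 278), App at 104 (87.4 to 89.8) and Pdk4 at 52.6 (22.0 to 26.1). Leaving this library out ended the trends of Asns, Phgdh, Psat1 and Abcc3.

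Elsewhere at 40 mg/kg, Dnajc11 was highest in replicate 3 at 40.2 CPM (36.2 to 36.6 in the others). Cyp7a1 was lowest in replicate 1 at 96.8 CPM (214 to 231). Replicate 2 was highest in Nr1d1 at 1.36 CPM (0.998 to 1.05) and in Lcn2 at 8.61 CPM (1.63 to 2.31). In xylazine 20 replicate 3, Scd was lowest at 2304 CPM (4812 to 5246) and Alb at 88177 CPM (112864 to 117516), while Bag3 was highest at 28.3 CPM (23.4 to 24.2). Replicate 1 of that dose was highest in Adgrg2 at 1.39 CPM (0.330 to 0.492) and in Gsta3 at 34.8 CPM (20.3 to 21.0), and lowest in Cps1 at 2609 CPM (3188 to 3300). Mcm10 was highest in xylazine 20 replicate 4 at 14.4 CPM (4.47 to 6.04).

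At 10 mg/kg, Fasn was highest in replicate 3 at 399 CPM (216 to 244), and replicate 1 was highest in Lpcat3 at 99.3 CPM (80.8 to 82.4) and in Ehhadh at 390.1 CPM (304 to 315). Replicate 4 was lowest in Rnf138 at 9.27 CPM (11.7 to 11.8) and in Banp at 5.33 CPM (6.76 to 6.98). In saline, replicate 1 was lowest in Baiap2l1 at 23.1 CPM (29.7 to 30.5) and in Asl at 174 CPM (223 to 232), and replicate 3 was highest in Cyp8b1 at 410.3 CPM (215 to 246) and lowest in Col4a2 at 18.5 CPM (21.3 to 21.8). Tmem135 was highest in saline replicate 2 at 66.8 CPM (52.2 to 53.8). Saline replicate 4 was lowest in Atp5mc1 at 86.5 CPM (93.8 to 94.6) and highest in Col1a1 at 16.99 CPM (7.00 to 7.98).

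Among lists, given as the mean log2 difference from saline, saline replicate 4 was highest in cholangiocyte markers at 1.35 (-0.53 to -0.33 in the others) and in acute phase genes at 0.36. Skeletal and smooth muscle markers were highest in xylazine 40 replicate 2 at 0.42 (-0.98 to -0.74). Cholesterol synthesis genes were lowest in xylazine 40 replicate 1 at -0.47 and growth hormone axis genes in xylazine 40 replicate 2 at -0.29. At 10 mg/kg, replicate 1 was lowest in inflammatory genes at -0.0692 and in gluconeogenesis genes at -0.0892, replicate 3 was lowest in urea cycle and amino acid catabolism genes at -0.26, and replicate 4 was highest in respiratory chain genes at 0.15.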

How the results depend on the processing

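The removal of 2 libraries together was chosen only after the data were seen. The counts below depend on the choices named, the cause was not tested unless the choice itself gives it, and 4 animals per group with 16059900 to 16956900 counts per library limit calls to large or tight changes and leave genes such as Adra2a untested.

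DESeq2 as the test called 51 genes at 20 mg/kg and 517 at 40 mg/kg against saline. It called 34 between 10 and 20, 7 between 20 and 40 and 286 between 10 and 40 mg/kg, 436 as genes changed in any dose and 750 with a trend. An adjusted p under 0.1, which admits more genes by construction, gave 2 at 20 mg/kg, 450 at 40 mg/kg, 4 between 10 and 20, 149 between 10 and 40, 113 for any dose and 779 with a trend. A minimum absolute log2 fold change of 1, which admits fewer, left 43 at 40 mg/kg, 24 between 10 and 40, 20 for any dose and 85 with a trend. Limma on log2 TPM gave 2 at 20 mg/kg with either 1 or 0.1 added, and 72 between 10 and 40 with 0.1 added. With no filter 1 gene passed between 10 and 20 mg/kg, and with the stricter filter 4. Fitting the compared groups alone, with fewer animals, gave 1 between 20 and 40 and 73 between 10 and 40. A block for the replicate number gave 1 between 20 and 40 and 25 for any dose. Replicate numbers showed little sign of pairing animals, since 5 of 16 libraries were closest to one with their own number. Deviations from the group mean had a median correlation of 0.000222 in pairs with the same number and -0.00179 in other pairs. The highest values were 0.279 and 0.186, so a pairing of some animals is not excluded. The trend among the 3 xylazine doses, with fewer animals and a narrower range, called 14. Leaving out xylazine 20 replicate 3 and xylazine 40 replicate 4 together gave 51 at 40 mg/kg, 8 between 10 and 40, 8 for any dose and 124 with a trend.

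Leaving out 1 library at a time gave 0 to 1 genes at 10 mg/kg, 0 to 19 at 20 mg/kg and 27 to 198 at 40 mg/kg against saline. It gave 0 to 6 between 10 and 20, 0 to 1 between 20 and 40 and 2 to 120 between 10 and 40, 6 to 89 for any dose and 127 to 405 with a trend. With the saline animals split 2 and 2, which removes shared controls by construction, the correlation across genes was 0.0221 for 10 and 20, 0.0132 for 10 and 40 and 0.262 for 20 and 40 mg/kg.

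DESeq2 size factors, total count scaling, limma-voom, FPKM and dose as its rank kept every total within 1.5 times, but not the split by direction. The trend went from 163 higher and 208 lower to 276 and 112 under total count scaling and to 218 and 84 with FPKM, and 40 mg/kg from 60 and 81 to 91 and 50 and to 89 and 56. Of 118 results for named genes, 109 kept their side of the threshold under total count scaling, all 118 under DESeq2 size factors, 105 under limma-voom and 112 under DESeq2. Leaving out the 2 libraries ended 49 of them. No passing result changed sign.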

Other observations

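Of the tests below, that of insulin was chosen only after the result was seen.

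Some clock genes stood on either side of saline at 40 mg/kg without passing, and the list was not called (camera adjusted p = 0.222, adjusted p with an estimated correlation 0.564). Per2 stood at a log2 fold change of 1.48 (adjusted p = 0.181) and Dbp at 1.04 (adjusted p = 0.101), while Per1 stood at -1.46 (adjusted p = 0.206) and Nr1d2 at -0.80 (adjusted p = 0.191). These 4 genes were chosen after their values were seen and did not pass over all genes. When adjusted over the list alone, 6 clock genes were higher and 3 lower at 40 mg/kg, and the core genes Arntl (-0.01) and Clock (-0.06) stood near 0.

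The glucocorticoid responsive list was not called at 40 mg/kg (camera adjusted p = 0.0653, adjusted p with an estimated correlation 0.564), with 13 of 18 negative and a median of -0.27. Pck1 and Zbtb16 passed over all genes, and 4 members passed when adjusted over the list alone, all lower. Cholangiocyte markers at 10 mg/kg had 10 of 11 negative and a median of -0.77 (camera adjusted p = 0.0301, adjusted p with an estimated correlation 0.625), in a comparison where saline replicate 4 lay 1.35 above the saline mean. Erythroid markers at 20 mg/kg had 7 of 8 genes negative and a median of -0.88 (camera adjusted p = 0.0464, adjusted p with an estimated correlation 0.802), in a comparison where saline replicate 4 lay 0.87 above the saline mean.

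The rise of lipogenic genes could come from several regulators. Activation of LXR would raise its other targets, but the median of 9 such genes was -0.10 (SE over genes 0.122) with 3 higher. These 9 were fixed beforehand and do not hold every target of LXR. The values argue against LXR activation for these 9 only, and a rise of other targets through LXR remains open. Activation of ChREBP would raise other carbohydrate response genes. The median of 7 was 0.13 (SE over genes 0.185) with 5 higher. ChREBP activation thus cannot be told apart from none, since the spread of so few genes covers both outcomes. Stronger insulin action would raise lipogenic genes and lower Pck1, Igfbp1 and Irs2. The mean of Igfbp1 and Irs2 was 0.36 (SE 0.413), with Igfbp1 at 0.83 and Irs2 at -0.11, so insulin action cannot be told apart from none with 2 genes that went opposite ways.

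Other splits of the same animals were fitted to see whether chance gives as many genes. Shares of splits were not adjusted over the comparisons. For 40 mg/kg against saline the real groups of 8 animals gave 94 genes and at most 3 came from any other split. Of the 35 splits 1, the real one, reached the real count. That argues against chance but does not exclude it, since the real split alone is the lowest share that splits can give. The same holds for 10 against 40 mg/kg, with 73 genes and at most 8 (1 of 35), for any dose, with 46 and at most 12 (1 of 100), and for the trend, with 371 and at most 20 (1 of 100). For 20 against 40 mg/kg the splits do not argue against chance, with 1 gene and at most 2 in other splits (6 of 35). For 10 mg/kg and for 20 mg/kg against saline and for 10 against 20 mg/kg the real count was 0, which all 35 of 35 splits reach whatever the data, so the splits decide nothing there. The highest counts of other splits were 6, 36 and 45. The split with 45 genes set xylazine 10 replicate 1 with xylazine 20 replicates 1, 2 and 3 against the rest, and the one with 36 set saline replicates 1, 2 and 4 with xylazine 20 replicate 4. In both, xylazine 20 replicate 4 stood with most animals of the lower group. Saline replicate 3 in the split with 36 genes, and xylazine 10 replicate 1 in that with 45, stood with xylazine 20 replicates 1, 2 and 3. On the first principal component these 2 lay at -4.54 and -4.68, above xylazine 20 replicate 4 at -7.24. Both splits thus point to a structure of the samples that does not follow dose alone.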
